A study of Mus musculus with 23 samples.

How the data were processed

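ChIP-seq peak lists of 5 libraries were analysed: p65 in thioglycollate-elicited mouse peritoneal macrophages of 2 genotypes (NCoR wild type and knockout), untreated or after 1 h of KLA, and biotin-tagged LXRβ in GW3965-treated RAW264.7 cells. The series also has 6 GRO-seq, 6 H3K4me2, 4 H4K5ac and 2 input samples, which were not analysed here because they had no processed file in the set used. Groups were taken from the sample titles, with 1 library in each, so no replicates of a group could be compared. No test between groups was run, and peaks were not treated as replicates.

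Reads were aligned with Bowtie 0.12.7 to mm9, and HOMER was used, per the submitters' processing notes. The HOMER version was not given in the sources used here. Peaks were called per library with findPeaks in factor mode, per the file headers, at a false discovery rate of 0.001. At most 1 tag per bp was considered, per the file headers, which caps the height of the tallest and narrowest peaks. Peaks also had to reach 4-fold over the surrounding 10000 bp with a Poisson p of 0.0001 and, where an input was used, 4-fold over input. The tag threshold was 5 for the p65 lists and 9 for LXRβ. The wild type KLA list was called without an input, per the file headers, while the 3 other p65 lists used a wild type macrophage input and the LXRβ list an input of the control line. The genome size setting was 2000000000 for the wild type KLA and LXRβ lists and 4000000000 for the others. Peak widths were fixed per list at 103 bp (untreated wild type), 126 bp (untreated knockout), 132 bp (KLA wild type), 144 bp (KLA knockout) and 121 bp (LXRβ), so a wider list can collect more tags per site and overlap more easily.

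The deposited normalized tag count, a signal value, is the number of tags at a peak per 10000000 tags of the library, per the file headers. The deposited findPeaks score is a whole number that equals the tags behind that signal in 4 lists. In the wild type KLA list it differed from those tags at 13561 of 30021 peaks. Over all peaks of that list it was on average 1.06 times as high, so heights there were counted in another way than in the others. The deposited count of total tags per peak (in the lists with an input) and the scaled input tags were used to describe peaks and in 1 alternative. The fold over local signal is the authors' ratio of tag densities, and the focus ratio is the authors' fraction of tags on the side their strand predicts. The deposited p-values were not used beyond the authors' own thresholds. Scores and folds are the authors' and were used only to describe, rank or filter peaks within a list, except for the score in the alternatives named below.

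Total tags were 777228 and 786121 in the untreated and 2120392 and 1673506 in the KLA libraries (wild type and knockout), and 11758634 for LXRβ. The lowest listed peaks rested on 5 tags, or 9 for LXRβ, and 63.8% of untreated wild type and 63.7% of untreated knockout peaks had 6 tags or fewer. A site absent from a list may hold tags below that threshold. Tags are not independent molecules, so intervals and thresholds cover counting error only.

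Lists were compared with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) by the share of peaks of a list overlapping a peak of another by 1 bp or more, with an exact Clopper-Pearson interval at 95%. Chance overlap was the mean after moving the list by 20 kb to either side. Moved peaks need not lie in regions open to binding, so this level does not account for sites that many factors share. The overlap code was tested on simulated lists, in which it found 100% of 11292 planted shared peaks for the KLA comparison and of 351 for the untreated comparison, and it gave the same numbers as bedtools 2.31.1 on all pairs of lists. Height ratios at shared sites used the overlapping peak with the nearest centre. The interval of a median is from order statistics, and that of a height is an exact Poisson interval of its tags. Alternatives were centres at most 100 bp apart, a reciprocal overlap of 50%, the upper part of a list by height, both lists cut to as many of their tallest peaks as 50% of the shorter list holds, a stricter height, autosomes and X only, and scaling by tags in peaks. Further alternatives were chosen after seeing the data: centres at most 500 bp apart, removal of peaks with 1 or more scaled input tags, equal lowest heights (at the lowest knockout KLA height and just above it), equal list lengths by trimming the longer list, and heights per bp, from the score, or from recounted tags.

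Sites named in the report followed a rule fixed before the data were examined, and the regions around the tallest LXRβ peaks in the closing section were chosen after. It took the 5 tallest peaks of each list, the 3 tallest peaks listed in only 1 genotype or only with or without KLA, the 5 tallest LXRβ peaks with a wild type KLA p65 peak, and the 3 windows of 100 kb with most peaks in each list. Gene names, coverage of 14 gene lists fixed in advance and motif shares were not reported: they needed a genome or annotation of mm9, and the reference table used here was of another build, so nothing was converted.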

Results

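Binding sites of p65 (RelA), the NF-κB subunit that enters the nucleus when macrophages meet bacterial lipids, were mapped by ChIP-seq in primary mouse macrophages with and without the nuclear receptor corepressor NCoR. The cells were peritoneal macrophages elicited with thioglycollate. Knockout macrophages came from mice with floxed NCoR alleles and a LysM-Cre transgene, and wild type macrophages from floxed mice without the transgene. Each genotype was studied untreated and after 1 h with 100 ng/ml Kdo2-Lipid A (KLA), the lipid A part of endotoxin and an agonist of the receptor TLR4. Sites of LXRβ, a nuclear receptor for oxysterols that controls cholesterol efflux and fatty acid synthesis genes, were mapped in the mouse macrophage line RAW264.7 carrying biotin-tagged LXRβ, after 2 h with 1 µM of the LXR agonist GW3965. Of the 23 samples of the series, these 5 had peak lists and are analysed here. Each group was 1 sample, so no difference below has a replicate check, no test between groups was run, and intervals cover counting error only.

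The untreated p65 libraries held 777228 tags (wild type) and 786121 tags (knockout). The KLA libraries held 2120392 tags (wild type) and 1673506 tags (knockout), and the LXRβ library held 11758634 tags. The name of the LXRβ tag set in the file header ends in "All", so these tags may come from more than 1 sequencing run pooled under that sample. Peak height is given as the authors' normalized tag count, in tags per 10000000 tags of the library. At these depths 1 tag was worth 12.9 in the wild type and 12.7 in the knockout untreated library, 4.72 in the wild type and 5.98 in the knockout KLA library, and 0.910 in the LXRβ library. Positions are on mouse build mm9. No gene annotation of that build was used, so sites are named by position alone, and NCoR itself was not measured by these lists.

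The first comparison asked where p65 bound before and after KLA. In wild type macrophages the list grew from 702 peaks to 30021, and in knockout macrophages from 2227 to 22585. The share of tags lying in peaks was 0.83% in untreated and 17.57% in KLA-treated wild type cells, and 2.37% and 17.66% in knockout cells. The tallest wild type KLA peak, at chromosome 19 from 6945450 to 6945582, reached a height of 679.1 (95% Poisson interval 573 to 800). It had no peak in untreated wild type or untreated knockout cells, and its height in KLA-treated knockout cells was 675.2. A site at chromosome 17 from 29532456 to 29532588 reached 622.5 in wild type and 699.1 in knockout cells after KLA. Neither untreated list overlapped it, although untreated wild type cells had a peak of 77.2 centred 159 bp away. At chromosome 10 from 77597969 to 77598101 the height was 598.9 in wild type and 573.6 in knockout KLA cells, again with no untreated peak.

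Other tall KLA sites were already listed in untreated cells. At chromosome 17 from 18037852 to 18037984 the height was 64.3 untreated and 650.8 after KLA in wild type cells, and 76.3 and 627.4 in knockout cells. At chromosome 17 from 13203058 to 13203190 it was 115.8 untreated and 641.4 after KLA in wild type cells. In knockout cells this site had no untreated peak and a height of 657.3 after KLA. At chromosome 13 from 20878976 to 20879108 the wild type height was 90.1 untreated and 636.7 after KLA, and the knockout height after KLA was 543.8. KLA peaks also came in clusters. In the 100 kb from position 75500001 of chromosome 14, wild type KLA cells had 20 peaks and knockout KLA cells 15, against 0 and 1 without KLA. The window from 115900001 of chromosome 5 held 19 and 14 KLA peaks, and that from 83400001 of chromosome 11 held 18 and 16. The windows from 8500001 and from 109200001 of chromosome 11 held 16 and 18, and 15 and 16. Neither untreated list had a peak in these last 4 windows. Other clusters were there before KLA. The 100 kb from 3000001 of chromosome 9 held 20 wild type and 13 knockout KLA peaks against 22 and 18 untreated peaks, and those from 102000001 of chromosome 11 held 15 and 14 against 11 and 13. Peaks of the chromosome 9 window had median scaled input tags of 2.25 (untreated wild type), 2.55 (untreated knockout) and 5.5 (knockout KLA). In the chromosome 11 window these were 0.1, 0.1 and 0.2, so the chromosome 9 cluster was also high in input.

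**Figure D1:**
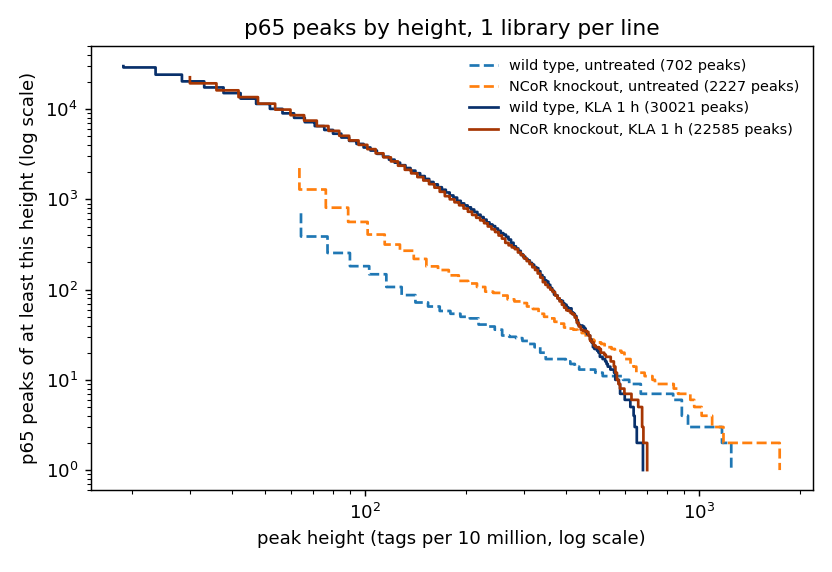
Number of p65 peaks (y axis, log scale) at or above each height (x axis, normalized tags per 10000000, log scale) in the 4 p65 libraries. The KLA lines of the genotypes run close together from a height of 29.9 upward, where the knockout list starts, while the untreated knockout line (2227 peaks) lies above the untreated wild type line (702 peaks) over nearly its whole length.

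Of the 702 untreated wild type peaks, 532 (75.8%, 95% Clopper-Pearson interval 72.4 to 78.9) overlapped a wild type KLA peak by 1 bp or more. Of the 2227 untreated knockout peaks, 922 (41.4%, 39.3 to 43.5) overlapped a knockout KLA peak. Lists moved by 20 kb gave 1.07% and 1.19%. Some tall untreated peaks were not listed after KLA. In wild type cells these included a peak of 669.0 at chromosome 2 from 98506771 to 98506873, with 4.2 scaled input tags and a wild type KLA peak of 523.5 centred 470 bp away, and peaks of 308.8 and 295.9 at chromosome 17 from 39984499 to 39984601 and from 39984955 to 39985057. Their fold over local signal was 5.97 on chromosome 2 and 6.58 at both chromosome 17 peaks. The median of that list was 80.1, and 4-fold was required. Whether the local filter took them from the KLA list was not tested. In knockout cells they included a peak of 1018 at chromosome 11 from 108873066 to 108873192, whose nearest knockout KLA peak lay 87120 bp away. A knockout peak of 559.7 at chromosome 5 from 147072597 to 147072723 had no knockout KLA peak within 387716 bp. The third, at chromosome 6 from 125827050 to 125827176 with a height of 648.8, had a knockout KLA peak of 77.7 centred 148 bp away. The knockout peaks on chromosomes 11 and 5 had 4.0 and 2.6 scaled input tags. The wild type KLA list, called without an input, had overlapping peaks of 127.3 and 51.9 at these sites. Whether the input filter took them from the knockout KLA list was not tested.

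The genotype comparison after KLA asked whether loss of NCoR changed where p65 went. The tallest sites were shared and of similar height. Besides those named above, the highest 5 knockout peaks held 681.2 at chromosome 2 from 98507219 to 98507363 (wild type 523.5) and 675.2 at chromosome 9 from 35112966 to 35113110 (wild type 499.9), at which the knockout list gave 13.1 and 16.8 scaled input tags. A total of 16203 wild type KLA peaks (54.0%, 53.4 to 54.5) overlapped a knockout peak, and 16202 knockout peaks (71.7%, 71.1 to 72.3) overlapped a wild type peak, against 0.928% and 1.23% by chance. The share found was higher for peaks with more tags. Of wild type peaks with 5 or 6 tags, 22.1% were found in the knockout list, against 97.8% (97.2 to 98.4) of the 2227 peaks with 30 or more. For knockout peaks the shares were 44.7% and 99.2% (98.4 to 99.6).

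**Figure D2:**
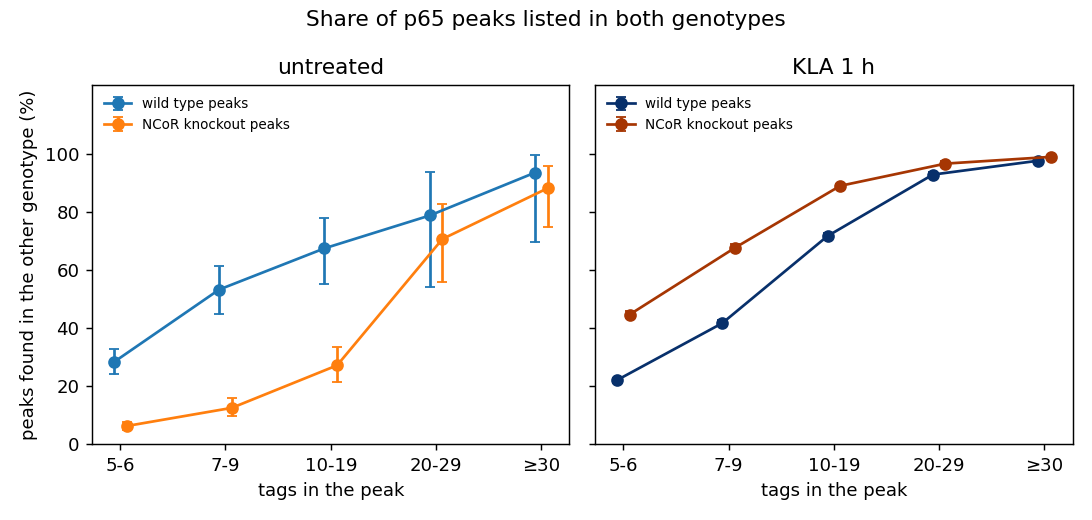
Share of p65 peaks (y axis, percent) that overlapped a peak of the other genotype by 1 bp or more, by the number of tags in the peak (x axis), for untreated (left) and KLA-treated cells (right). Points are shares of 1 list and bars are 95% Clopper-Pearson intervals. After KLA, 97.8% of wild type and 99.2% of knockout peaks with 30 or more tags were found in the other genotype.

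The tallest peaks listed in only 1 genotype after KLA had a neighbour in the other list. The wild type peak at chromosome 5 from 118803857 to 118803989 (278.3) had a knockout peak of 191.2 centred 301 bp away. Those at chromosome 4 from 119705153 to 119705285 (250.0) and chromosome 6 from 17714453 to 17714585 (240.5) had knockout peaks of 167.3 at 161 bp and 239.0 at 323 bp. The knockout peak at chromosome 12 from 102016922 to 102017066 (245.0) had a wild type peak of 141.5 at 156 bp. Those at chromosome 15 from 64054038 to 64054182 (239.0) and from 59312833 to 59312977 (221.1) had wild type peaks of 113.2 at 161 bp and 150.9 at 177 bp.

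At the 16203 shared KLA sites the median height ratio of knockout to wild type was 1.09 (95% interval 1.07 to 1.09, by order statistics over peaks), with quartiles of 0.845 and 1.40. The ratio was 2 or more at 1017 sites and 0.5 or less at 394. Knockout peaks were 144 bp wide and wild type peaks 132 bp, and per bp of peak the median ratio was 0.996, with 648 sites at 2 or more and 667 at 0.5 or less. With the tags at calling in both lists there were 735 and 485. The wild type list was called without an input and the knockout list with 1. The excess of 7436 wild type peaks depended on the lowest height. At 29.9 or more, the lowest knockout height, 20345 wild type peaks stood against 22585 knockout peaks, a difference of -2240, and the shares found in the other genotype changed order, to 68.3% of wild type and 61.6% of knockout peaks. Just above that height, without the lowest tag step of the knockout list, 20345 stood against 19353, a difference of 992, and the shares were 65.1% and 68.4%. Both shares count nearly the same overlapping peaks, so the shorter list has the higher share.

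**Figure D3:**
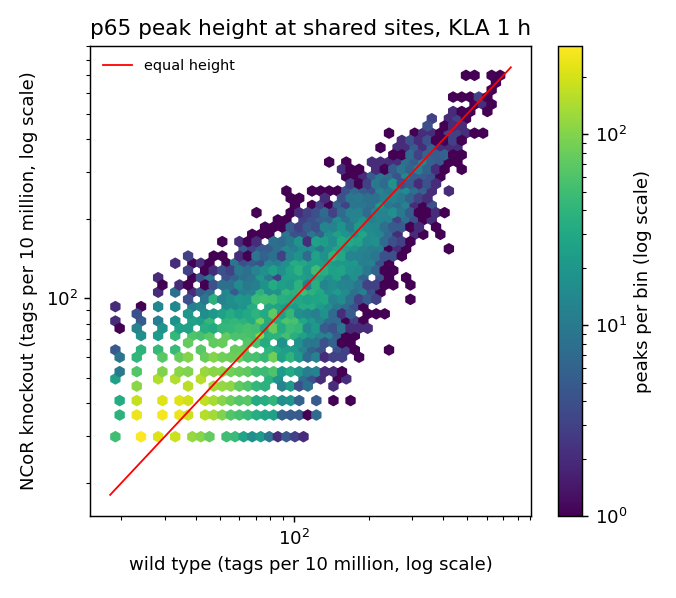
Height of p65 peaks after KLA in wild type (x axis) and knockout cells (y axis), both in normalized tags per 10000000 on log scales, at the 16203 shared sites. Colour gives the number of peaks per bin on a log scale, and the red line marks equal height. The sites lie around the line, with a median ratio of 1.09, and the lower edge at 29.9 is the lowest height of the knockout list.

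In untreated cells, where the comparison asked whether p65 was bound without a stimulus when NCoR was absent, the knockout list held 3.17 times as many peaks as the wild type list, with 1.01 times as many total tags. Both were called with the same input and tag threshold, but peaks were 126 bp wide in the knockout and 103 bp in the wild type list. A wider peak can reach the threshold of 5 tags more easily. The tallest knockout peak, at chromosome 17 from 4626283 to 4626409, reached 1743 (1463 to 2060). The wild type list had a peak of 257.3 centred 170 bp away. At chromosome 11 from 25000108 to 25000234 the height was 966.8 (762 to 1210) in knockout and 347.4 in wild type cells. At chromosome 11 from 108873066 to 108873192 it was 1018 (807 to 1267) in knockout and 347.4 in wild type cells. Knockout peaks of 559.7 (407 to 751) at chromosome 5 from 147072597 to 147072723 and of 521.5 (374 to 708) at chromosome 10 from 36983525 to 36983651 had no wild type peak within 500 bp. The peaks on chromosome 11 from 108873066 and on chromosome 5 had 4.0 and 2.6 scaled input tags in the knockout list, and the other 3 at most 0.1. After KLA these sites were lower or not listed in knockout cells. The knockout KLA height was 203.2 at the chromosome 17 site and 155.4 at chromosome 11 from 25000108. The other sites overlapped no knockout KLA peak. In the order named, the wild type KLA heights were 84.9, 84.9, 127.3, 51.9 and 23.6. Why the sites were lower after KLA was not tested.

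Other tall untreated sites were of similar height in both genotypes. They lay at chromosome 2 from 98507241 to 98507343 (wild type 1248, knockout 1094) and from 98502882 to 98502984 (887.8 and 941.3), and at chromosome 9 from 35112989 to 35113091 (1171 and 1183). Also at chromosome 9, the sites from 3035797 to 3035899 (926.4 and 865.0) and from 3025449 to 3025551 (887.8 and 839.6) belonged to the 100 kb from 3000001, which held 22 wild type and 18 knockout peaks. The wild type list gave these 5 sites 3.7 to 5.6 scaled input tags. At the 255 shared untreated sites with less than 1 scaled input tag in the wild type list, the median knockout to wild type ratio was 1.32 (1.19 to 1.38). At the 29 sites with more it was 0.821 (0.706 to 0.934). Untreated knockout peaks were 126 bp wide and wild type peaks 103 bp, and per bp of peak these ratios were 1.08 (0.970 to 1.13) and 0.671 (0.577 to 0.763).

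Over whole lists, overlap between the genotypes was lower than after KLA. By tag number it was lower too, except among wild type peaks with 5 to 9 tags. Of wild type untreated peaks, 284 (40.5%, 36.8 to 44.2) were in the knockout list, and they made up 12.8% (11.4 to 14.2) of that list. With the knockout list cut to its 702 tallest peaks, the length of the wild type list, this share was 26.9% (23.7 to 30.4), and with both lists cut to as many tallest peaks as 50% of the shorter list holds, 34.2% both ways against 70.6% after KLA. Chance levels were 0.214% and 0.0674%. Among wild type peaks 28.3% of those with 5 or 6 tags and 53.4% of those with 7 to 9 were found in the knockout list, against 22.1% and 41.8% after KLA. Among knockout peaks with 5 or 6 tags 6.28% were found in the wild type list, and among those with 30 or more tags 88.4% (74.9 to 96.1). After KLA these shares of knockout peaks were 44.7% and 99.2%. The same tag number stands for a greater height in the untreated libraries. Of the 1943 peaks listed only in knockout cells, 820 (42.2%, 40.0 to 44.4) overlapped a wild type KLA peak, against 1.13% by chance. Of the 418 peaks listed only in wild type cells, 309 (73.9%, 69.4 to 78.1) did. The peaks listed only in wild type cells included 257.3 at chromosome 12 from 75905397 to 75905499, with 2.8 scaled input tags, and the peaks from 98506771 of chromosome 2 and from 39984499 of chromosome 17 named above. The peak on chromosome 2 had a knockout peak of 1094 centred 467 bp away. In the 100 kb from 102000001 of chromosome 11 both untreated lists had a cluster, of 11 wild type and 13 knockout peaks. From 174100001 of chromosome 2 there were 6 wild type and 0 knockout peaks, and from 104300001 of chromosome 11 there were 0 wild type and 9 knockout peaks.

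LXRβ sites were set beside the p65 sites because NCoR represses LXR target genes. The lists come from different cells, so overlap means the same position in the genome, not binding in the same cell. GW3965-treated RAW264.7 cells had 2743 LXRβ peaks. The tallest was at chromosome X from 103382247 to 103382367, with a height of 146.5 (125 to 171), and the site was also in all 4 p65 lists, at 77.2 and 127.2 untreated and 42.4 and 89.6 after KLA in wild type and knockout cells. The next, at chromosome 13 from 97363709 to 97363829 (113.8) and from 45487022 to 45487142 (109.2), overlapped no p65 peak, nor did the peak at chromosome 11 from 120685997 to 120686117 (98.3). KLA p65 peaks were centred 856 bp (wild type) and 710 bp (knockout) from the peak at 45487022. A wild type KLA peak was centred 622 bp from the peak at 120685997. For the peak at 97363709 the nearest p65 peak lay 45684 bp away. The LXRβ peak at chromosome 11 from 108873178 to 108873298 (107.4, with 26.0 scaled input tags) overlapped untreated p65 peaks of both genotypes and a wild type KLA peak of 127.3.

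Other tall LXRβ peaks with p65 after KLA lay at chromosome 4 from 53128847 to 53128967, at chromosome 9 from 25316575 to 25316695 and at chromosome 17 from 31204103 to 31204223. Their LXRβ heights were 98.3, 91.9 and 88.3. The p65 heights in wild type and knockout KLA cells were 70.7 and 77.7 at the first, 108.5 and 113.5 at the second, and 80.2 and 83.7 at the third. None of these 3 overlapped an untreated p65 peak. In all, 1162 LXRβ peaks (42.4%, 40.5 to 44.2) overlapped a wild type KLA p65 peak and 955 (34.8%, 33.0 to 36.6) a knockout one, against 1.00% and 0.784% by chance. The chance level, from moved peaks, cannot tell a link between p65 and LXRβ from regions open to many factors. With the wild type list limited to its 22585 tallest peaks, the length of the knockout list, its share was 37.2% (35.4 to 39.1). This cut fell among peaks tied at a height of 28.3. The wild type and knockout shares are over the same 2743 LXRβ peaks, so their separate intervals do not measure the difference between them. A total of 778 LXRβ peaks overlapped p65 in both genotypes after KLA, and 1404 in neither. Untreated p65 peaks covered 98 LXRβ peaks (3.57%, 2.91 to 4.34) in wild type and 200 (7.29%, 6.35 to 8.33) in knockout cells, whose list was 3.17 times as long. Per p65 peak the order was the other way, with an LXRβ peak at 14.0% (11.5 to 16.7) of untreated wild type and 8.98% (7.83 to 10.2) of untreated knockout peaks.

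The 100 kb window with most LXRβ peaks, from 141100001 of chromosome 4, held 10 of them, with 8 wild type and 5 knockout KLA p65 peaks, and the 100 kb from 140900001 of that chromosome held 8, with 5 and 3. The window from 43400001 of chromosome 13 also held 8 LXRβ peaks, with 3 wild type KLA p65 peaks and 0 knockout KLA p65 peaks. The tallest of these 3 was 23.6, below the lowest height of the knockout KLA list (29.9), so that list could not show peaks of such height. None of these windows had an untreated p65 peak in either genotype.

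**Figure D4:**
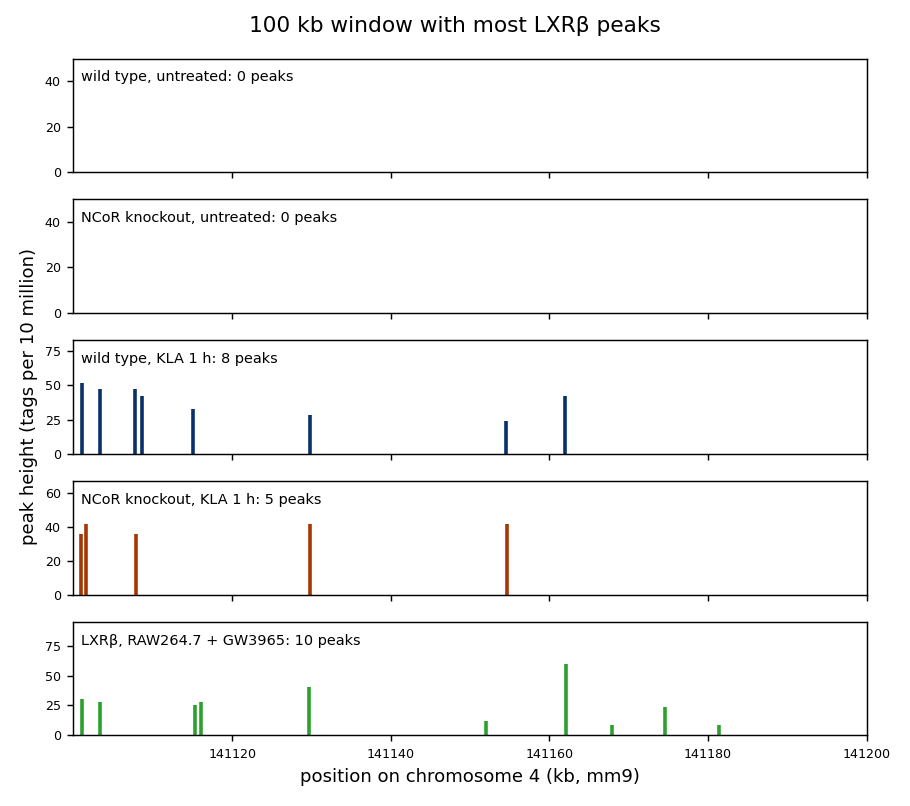
Peaks in the 100 kb window of chromosome 4 (mm9) with most LXRβ peaks. The x axis is the position in kb and the y axis the peak height in normalized tags per 10000000, scaled per panel, and each bar is 1 peak. The window held 10 LXRβ peaks, 8 wild type and 5 knockout p65 peaks after KLA, and 0 untreated p65 peaks.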

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

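The median change in height with KLA had opposite signs in the genotypes, each taken over its own untreated peaks that were still listed after KLA. The median log2 ratio of KLA to untreated height was 0.36 (interval 0.21 to 0.60) at 532 wild type peaks and -0.090 (-0.24 to -0.089) at 922 knockout peaks, which are different sets of sites. In knockout cells 154 of these sites were 2-fold or more higher and 158 2-fold or more lower after KLA, and in wild type cells 171 and 114. This comparison was chosen after the data were seen, and the difference between the genotypes was not tested, since each group was 1 library. The peak width, fixed per list, was 103 bp untreated and 132 bp after KLA in the wild type lists, and 126 and 144 bp in the knockout lists. Per bp of peak the medians were 0.00093 (-0.14 to 0.24) and -0.28 (-0.43 to -0.28), so the signs were no longer opposite beyond the interval. Without peaks of 1 or more scaled input tags the medians were 0.55 at 497 wild type and -0.089 at 902 knockout peaks. At the 197 sites listed in all 4 p65 libraries they were -0.01 (-0.45 to 0.50) and 0.05 (-0.26 to 0.30), so no opposite change was seen at the same sites. Peaks enter the untreated lists only from a height of 64.3 (wild type) or 63.6 (knockout), against 18.9 and 29.9 after KLA.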

How the results depend on the processing

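Of 91 alternative values, 29 stayed within the interval (shares and height ratio) or within 1.5 times (peak numbers), 60 moved beyond it and 2 changed sign. Alternatives with centres at most 500 bp apart, equal lowest heights, trimmed lists, input tags removed, heights per bp, from the score or from recounted tags were chosen after seeing the data. Causes were not tested unless stated. The order of the untreated shares (wild type above knockout) held under every setting run on both, except both lists cut to equal numbers of tallest peaks in the genotype comparison, where both were 34.2% by construction. The order of the KLA shares (knockout above wild type) turned at the lowest knockout height and turned back just above it, and that of the LXRβ shares (wild type above knockout) at equal numbers of tallest peaks. In the genotype comparisons, untreated or after KLA, both shares count nearly the same overlapping peaks where neither or both lists are cut. Their order there follows the list lengths, so its holding or turning says nothing about genotype.

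With centres at most 100 bp apart, the shares were 50.8% for wild type KLA peaks in knockout KLA, 67.6% for the reverse, and 37.9% and 31.1% for LXRβ peaks with wild type and knockout KLA p65. Reciprocal overlap of 50% gave 44.4%, 59.0%, 27.1% and 22.4% for these, 35.8% and 11.3% for untreated wild type peaks in knockout and the reverse, 60.8% and 33.0% for untreated wild type and knockout peaks found after KLA, and 33.6% for knockout-only untreated peaks in wild type KLA. Centres at most 500 bp apart gave 59.9% and 78.0% (KLA, genotypes), 81.1% and 45.9% (untreated, found after KLA), 46.7% (knockout-only) and 53.8% and 43.7% (LXRβ). The upper part by height of the list asked about gave 77.5% and 89.6% (KLA, genotypes), 54.1% and 20.04% (untreated, genotypes), 80.6% and 43.5% (found after KLA) and 37.0% (LXRβ with knockout). Both lists cut to as many tallest peaks as 50% of the shorter list holds gave 70.6% both ways (KLA, genotypes), 34.2% both ways (untreated), 16.8% and 7.55% (found after KLA), 3.50% (knockout-only) and 4.38% and 4.52% (LXRβ). In these last comparisons the KLA list is many times the longer, so the cut removes nearly all of it.

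Limiting both KLA lists to the lowest knockout height gave 68.3% for wild type and 61.6% for knockout peaks, and 66.6% and 63.4% with the tags at calling. Just above that height, without the lowest knockout tag step, they were 65.1% and 68.4%, and 63.1% and 70.2% with the tags at calling. The difference in peak number, 7436 in favour of wild type, became -2240, or -1067 with the tags at calling, at the lowest knockout height, and 992 or 2165 just above it. A wild type KLA list as long as the knockout list gave 71.1% (untreated wild type found after KLA), 37.9% (knockout-only) and 37.2% (LXRβ). An untreated knockout list as long as the wild type list gave 26.9% (in wild type) and 44.0% (after KLA). The height ratio at shared KLA sites was 1.01 in the upper part by height, 0.996 per bp of peak, 1.04 with the tags at calling in both lists and 1.04 with recounted tags. At 2 times the lowest height of any list 450 LXRβ peaks remained, while no p65 list lost a peak, by construction. Gene list coverage and motif share, with their alternatives, were not run. No paired analysis was possible because each group was 1 sample and no 2 groups shared more than 1 replicate number. Depth limits the untreated lists most, where 1 tag is a step of about 12.9 in height and 5 tags make a peak.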

Other observations

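All tests in this part were chosen after the results they bear on were seen. Untreated peaks of both genotypes fell into parts that met LXRβ sites to different degrees. Of the 1004 knockout-only peaks at no KLA peak of either genotype, 39 (3.88%, 95% interval 2.78 to 5.27) overlapped an LXRβ peak. Of the 939 knockout-only peaks at a KLA peak it was 111 (11.8%, 9.83 to 14.1), and of the 246 in both untreated lists and at a KLA peak 46 (18.7%, 14.0 to 24.1). Of the 38 in both untreated lists but at no KLA peak it was 4 (10.5%, 2.94 to 24.8). The parts also differed in height in the knockout list, with median tags of 6 in both knockout-only parts, 9 in the 246 peaks and 11 in the 38. The 1004 peaks had a median fold over local signal of 107 against 58.8 for the 939. The shares of the first 3 parts in wild type cells were 5.49% (1.81 to 12.4), 13.1% (9.68 to 17.3) and, for the third part, which is the same 246 sites in both lists, again 18.7%. The intervals of the first 2 wild type parts overlap. For the fold over local signal the order in wild type cells was the other way, 68.6 for the 91 peaks of the first kind and 72.1 for the 327 of the second. A total of 40 LXRβ peaks were in all 5 lists.

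The 100 kb around the tallest 10 LXRβ peaks, a choice made after the data were seen, differed in p65. Around the peak from 53128847 to 53128967 of chromosome 4 there were 6 LXRβ peaks, 8 wild type and 9 knockout KLA p65 peaks, and 1 wild type and 3 knockout untreated peaks. Around the peak from 120482028 to 120482148 of chromosome 11 there were 6 LXRβ, 5 wild type and 1 knockout KLA peaks, with 0 wild type and 1 knockout untreated peaks. Around that from 44358696 to 44358816 of chromosome 19 the numbers were 5 LXRβ, 4 wild type and 6 knockout KLA peaks, with no untreated peak. The other 7 regions held 1 or 2 LXRβ peaks each.

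The untreated knockout list was 3.17 times as long as the untreated wild type list. A deeper library is argued against by total tags 1.01 times as many, and the input and local filters by a ratio of putative peaks before these filters of 2.99. Binding, or reads, at KLA sites would not cover all of it, since 42.2% (40.0 to 44.4) of the knockout-only peaks had no KLA peak of either genotype within 2 kb. Reads carried over from the knockout KLA library in proportion to its peaks, as the source of all listed low KLA peaks, are argued against too. The tallest 10% of those KLA peaks were listed in untreated knockout cells in 10.1% (8.84 to 11.4). The 1.06% of the lowest 10% would lead to 87.0% under a Poisson model. With knockout-only untreated peaks the 2 shares were 5.76% and 0.841%. A smaller carry-over, with low peaks listed for another reason, is not addressed by these values. What stays open is the genotype, untested, a smaller carry-over, and any other difference between the 2 libraries. The share of tags in peaks also differed (2.37% against 0.83%), and each group was 1 library. Knockout peaks were also wider, 126 bp against 103 bp, and the effect of width on the number of peaks was not tested.

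Some tall KLA peaks were listed in 1 genotype only. A candidate explanation is that the caller centred the same site at another position. Of 224 wild type peaks with 20 or more tags and no overlapping knockout peak, 134 (59.8%, 53.1 to 66.3) had one within 500 bp, against 5.58% by chance. Of 67 such knockout peaks, 61 (91.0%, 81.5 to 96.6) did, against 5.22%. The 90 wild type and 6 knockout peaks without such a neighbour are not covered by it.

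The wild type KLA list was 1.33 times as long as the knockout KLA list, and its lower starting height, 18.9 against 29.9, is a candidate explanation that the tests leave open. At calling both lists started at 5 tags, and 18.9 was counted in another way than 29.9. The wild type library held 1.27 times as many total tags and gave 1.30 times as many putative peaks. This difference in depth was not tested and stays open too. At the lowest knockout height the ratio was 0.901, or 0.953 with the tags at calling, and just above it 1.05, or 1.11 with the tags at calling, past the 1.1 set as the bound for this explanation. At heights of 50, 100, 200 and 500 or more it was 0.993, 0.935, 1.08 and 0.864, or 1.07, 1.00, 1.15 and 0.955 with the tags at calling, on no steady side of 1. The input filter, which was applied to the knockout list only, removed peaks amounting to 25.6% of the difference, too few to be its whole cause. A genotype effect on weak sites below the knockout list's starting height stays open and was not tested.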
